A study of Sus scrofa with 15 samples.

How the data were processed

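Mature microRNAs (miRNAs) were measured by small RNA sequencing in peripheral whole blood of domestic pigs at 5 ages, 0, 30, 60, 180 and 360 days, with 3 biological replicates per age, 15 libraries in all. Total RNA was extracted with a mirVana kit and libraries were made with standard Illumina chemistry, per the labels' protocols. The labels also give the molecule as polyA RNA, which was not used here. CASAVA 1.8.2 and HISAT2 2.0.4 are named in the submitters' processing notes, without their roles. The counting tool, the miRNA annotation release and the genome build are not given in the sources used here, so no coordinates are printed.

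The deposited table lists 295 miRNAs with a read count and a TPM value per library. The deposited counts are whole numbers and sum to between 5774130 and 9977755 per library, and 230 to 268 miRNAs had at least 1 count. The deposited TPM values equal the count scaled by 1 total per library, with no term for length. That total exceeded the sum of the listed counts by between 0.0173% and 0.352%. Counts were tested, and TPM values served only as an alternative. Reads carry no molecular identifiers as far as the sources used here tell, so counting precision is an upper limit on the precision of a level. A count of 0 allows up to 3 counts, or 0.301 to 0.52 CPM before scaling, counting error only.

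In 2 cases a miRNA repeated another in every library: miR-199b-3p equalled miR-199a-3p, and miR-9-1 equalled miR-9. Each pair was kept once, which left 293 miRNAs. This departs from the plan of testing the counts as deposited and was decided after the table was seen. Reads of miR-199a-3p and miR-199b-3p cannot be told apart, and members of the let-7 family that differ by few bases may share reads in the same way. Some miRNAs on the lists below, among them let-7b and miR-223, were not analysed here.

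Counts were analysed in R 4.3.3 with edgeR 4.0.16. The default edgeR expression filter by age (minimum count 10, minimum total 15) kept 215 miRNAs and removed 78. Libraries were scaled with TMM factors, which ranged from 0.669 to 1.85. One quasi-likelihood model with a coefficient per age was fitted to all 15 libraries, so that every comparison shared 1 estimate of the spread. An F test asked whether a miRNA differed across the 5 ages. Contrasts compared each age with the preceding age, and day 360 with day 0. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and an adjusted p under 0.05 counted as a change. Standard errors (SE) of log2 fold changes were derived from the fold change and its F statistic. Levels are CPM scaled by the TMM factors, as mean ± SD over 3 libraries.

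For each contrast, the text names up to 10 miRNAs with the largest rise and 10 with the largest fall, with a mean of at least 50 CPM at either age and no overlap between the libraries of both ages. Across ages, it names the 10 with the lowest p and a mean of at least 50 CPM at some age. The 5 most abundant miRNAs and up to 4 of the most abundant members of each list are also covered by this rule. Some other miRNAs are named too, among them called list members and calls of alternative runs, and not each of these is marked in the text. The design, this rule, the lists and all but 2 of the alternatives were fixed before the data were examined.

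The 16 lists were the let-7 family, erythroid, myeloid, lymphoid, platelet, innate immune response, the miR-17~92 cluster with its paralogues, the miR-15/16 family, the miR-29 and miR-30 families, the DLK1-DIO3 cluster, HOX loci, the miR-99/100 family, muscle, liver, epithelial and brain. Some miRNAs stand on more than 1 list. Lists with at least 3 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 14 lists tested in a comparison. Camera was repeated with an estimated correlation. Calls of members were also adjusted over the list alone.

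The edgeR contrasts were tested on simulated counts drawn from the means of the real libraries. In each of 20 datasets of about 212 tested miRNAs, 14 miRNAs were changed at each fold size. For day 360 against day 0, 6.79% of 2-fold, 51.8% of 4-fold and 80.4% of 8-fold changes were called, and 5.12% of the calls were false. For day 30 against day 0, these shares were 6.43%, 53.2% and 80.0%, with 4.63% false calls. Each miRNA was drawn with the same spread in every library. The shares therefore do not cover an age with a deviant library, such as day 0 replicate 3. In simulated datasets with a let-7 family raised 4-fold at day 30, camera called it in 20 of 20. The miRNAs were drawn independently, so this does not test camera where list members are correlated.

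Alternatives were DESeq2 size factors in edgeR, library totals only, no low-count filter, a minimum of 10 CPM in 3 libraries, DESeq2 1.42.0, limma on log2(TPM + 1), only the libraries of both ages, a fold of at least 2, the replicate number as a block, the miRNAs over 10% of any library left out, and each library left out in turn. Added after the data were seen were voom with library quality weights and keeping the repeated miRNAs. With a library left out, the low-count filter was applied anew with fewer libraries in the smallest age. The tested miRNAs and lists could therefore differ between these runs.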

Results

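Peripheral blood of pigs was profiled for miRNAs at birth (day 0), at weaning (day 30), at day 60, and in sexually mature animals at days 180 and 360, with 3 libraries per age. The design asked how blood miRNAs change while the immune system develops. Libraries held between 5774130 counts (day 0 replicate 2) and 9977755 counts (day 360 replicate 1).

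The 5 miRNAs of highest mean normalised CPM were miR-451, made in red-cell precursors, with 35.3% of the counts on average, miR-148a-3p with 10.6%, let-7i with 8.06%, miR-92a of the miR-17~92 cluster with 5.93% and miR-7 with 3.22%. By mean share of counts, let-7g (3.44%) lay above miR-7. At day 0, miR-92a (13.3%) and miR-486 (7.04%) held larger mean shares than miR-148a-3p (3.62%) and let-7i (1.90%). The share of miR-451 was 7.47%, 8.97% and 59.4% in the 3 newborn libraries, and averaged 36.5% ± 7.1 at day 30, 34.3% ± 2.75 at day 60, 45.2% ± 7.06 at day 180 and 35.3% ± 5.75 at day 360 (SD, n = 3). TMM factors averaged 1.41 ± 0.304 at day 0, 1.24 ± 0.563 at day 30 and 0.699 ± 0.028 at day 360 (SD, n = 3). Day 30 replicates 1, 2 and 3 had factors of 1.13, 1.85 and 0.744.

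Replicates of an age were not duplicates of one another. The median absolute log2 difference between replicates was 1.72 and 1.56 for newborn replicate 3 against newborn replicates 1 and 2, and between 0.33 and 1.18 for the other pairs. The first principal component held 44.5% of the variance, and newborn replicates 1 and 2 lay at -25.0 and -23.5 on it, with newborn replicate 3 at -3.23.

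**Figure D1:**
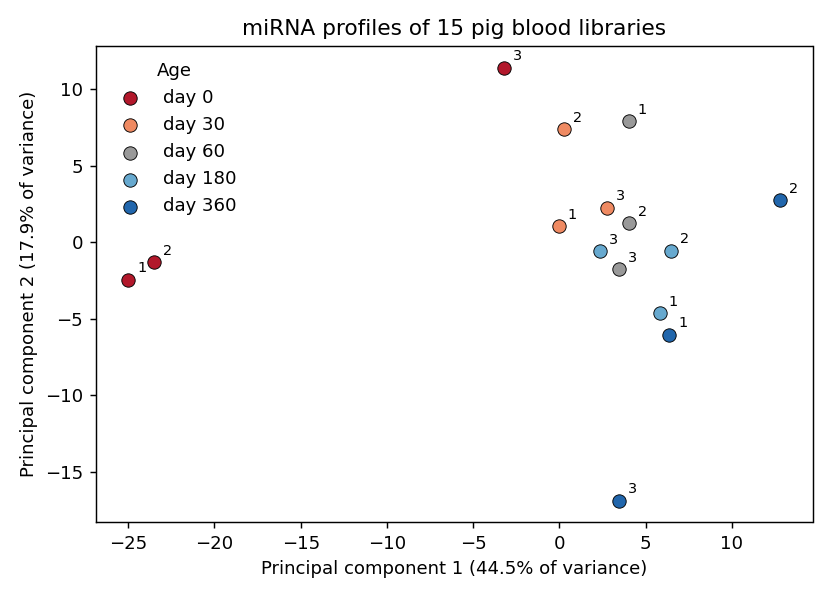
Principal components 1 and 2 of log2 CPM of 15 libraries, coloured by age and numbered by replicate. Newborn replicates 1 and 2 lie at -25.0 and -23.5 on component 1, and newborn replicate 3 at -3.23 lies nearer to the older libraries.

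Across the 5 ages, 61 of 215 miRNAs changed (edgeR F test). The mean was highest at day 0 for 37 of them, beside 86 of all 215 tested, and lowest at day 360 for 23. miR-199a-3p, abundant in platelets and mesenchymal cells, fell from 170 ± 79.0 normalised CPM at day 0 to 10.4 ± 2.89 at day 30 and 4.85 ± 2.98 at day 360 (SD, n = 3; adjusted p = 6.14e-06). miR-210, the miRNA induced by hypoxia through HIF, had means of 127, 42.1, 12.8, 2.48 and 1.66 normalised CPM at days 0, 30, 60, 180 and 360, the last 0.752 without day 360 replicate 1. miR-29a, which represses collagens and DNA methyltransferases, was lowest at day 0 at 79.6 ± 9.3 normalised CPM and highest at day 60 at 934 ± 131. The other miRNAs of lowest p were miR-1296-5p, miR-7134-5p, miR-339-5p, miR-4334-3p, miR-296-3p, miR-148b-3p and miR-2320-5p, all highest at day 0. The count was 126 without newborn replicate 3 and 37 without newborn replicate 2.

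**Figure D2:**
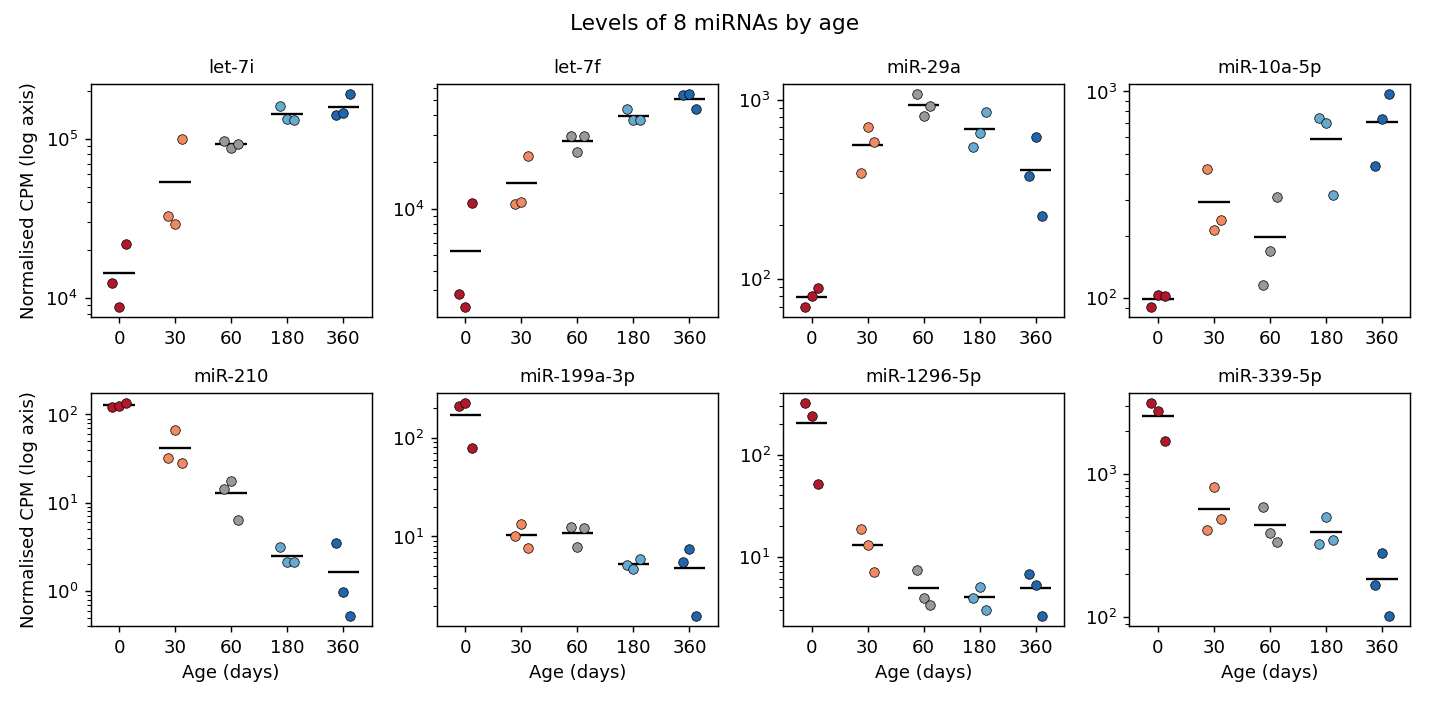
Normalised CPM (log axis) of 8 miRNAs against age in days; each point is 1 library and each bar the mean of 3. miR-210 means run from 127 at day 0 to 1.66 at day 360, and let-7i means from 14401.3 to 159249.

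From birth to day 30, 35 of 215 miRNAs changed, 9 up and 26 down. miR-182, of the miR-183/96/182 cluster on the erythroid list, rose by a log2 fold change of 3.36 ± 0.68 (SE, n = 3 per age; edgeR adjusted p = 0.00418), from 72.0 to 738 normalised CPM; the day 30 libraries were at 1707.75, 198 and 307, and without replicate 1 of that age the change was 1.86 (adjusted p = 0.0304). miR-29a rose by 2.81 ± 0.42 (adjusted p = 0.000569) and miR-155-5p, induced in activated lymphocytes and macrophages, by 1.62 ± 0.44 (adjusted p = 0.0226). let-7i rose by 1.91 ± 0.51 (1.15 without day 30 replicate 3, adjusted p = 0.182), miR-99a by 1.88 ± 0.45, miR-24-1-5p by 1.92 ± 0.56 and miR-10a-5p, encoded in a HOX cluster, by 1.56 ± 0.47. At day 30 let-7i held 5.53% ± 1.84 of the counts, but averaged 53982 ± 39634.9 normalised CPM (SD, n = 3). The TMM factor of day 30 replicate 3 was the lowest of that age, so the dependence of let-7i on this library may rest partly on scaling. Of the falls, miR-199a-3p changed by -4.03 ± 0.60 (adjusted p = 0.000569), miR-1296-5p by -3.97 ± 0.67, miR-504 by -2.97 ± 0.67, miR-7134-5p by -2.85 ± 0.53, miR-339-5p by -2.16 ± 0.45, miR-30a-3p by -1.66 ± 0.52 and miR-4334-3p by -1.61 ± 0.42. Of the 35, 25 had no overlap between the ages, and 23.3% of all tested miRNAs had none, against 10% by chance. In the later age steps, where no miRNA was called, this share was 18.6%, 16.3% and 19.5%. Changes too small for a call may be present there, so these shares set no level for ages without change. What an excess over 10% stands for was not tested. miR-7136-5p was also called higher, at 142 normalised CPM in day 30 replicate 1 and at 0 and 0.148 in the other libraries of that age, and its log2 fold change was -1.16 without replicate 1 of that age (adjusted p = 0.798); it was singled out after its values were seen.

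Of the 4 tested members of the muscle list, miR-206 changed by -6.55 ± 1.18 and miR-133a-3p by -4.49 ± 0.89, while miR-1 and miR-499-5p did not pass the test. miR-206, a skeletal-muscle miRNA, was at 23.2, 4.76 and 43.1 normalised CPM in the newborn libraries and at 0.28 on average at day 30, below the level of 3 counts. miR-127, the member of the imprinted DLK1-DIO3 cluster that could be tested, fell from 43.4 ± 29.9 (a mean of 28.8 without newborn replicate 1) to 1.81 ± 0.65 normalised CPM (log2 fold change -4.57 ± 1.03, adjusted p = 0.00691). No list passed camera at this age step, at the lowest adjusted p of 0.142, but this depended on the low-count filter. With no low-count filter 7 passed, 5 upward (let-7, erythroid, lymphoid, innate immune response and miR-17~92) and 2 downward (muscle and the DLK1-DIO3 cluster), and none of them with an estimated correlation (adjusted p from 0.263 to 0.521). With 1 library left out, the erythroid list passed without day 30 replicate 2 (adjusted p = 0.0295; 0.224 with an estimated correlation) and the muscle list without newborn replicate 2 (adjusted p = 0.0447; 0.347 with an estimated correlation). The DLK1-DIO3 cluster became testable, with 6 members, only in runs holding both newborn replicates 1 and 2. These members then passed the filter by being high in those 2 libraries, so its lower values in such runs are no further support. In the HOX loci list, miR-10a-5p and miR-10a-3p rose and miR-10b fell. The miR-29 and miR-30 families list held 1 riser, miR-29a, and 3 fallers, miR-30a-3p, miR-30c-3p and miR-30c-1-3p.

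The count at day 30 against day 0 was 126 without newborn replicate 3. It was 17 without newborn replicate 1, 16 without newborn replicate 2, and 18, 23 and 21 without day 30 replicates 1, 2 and 3. Of the named miRNAs, miR-24-1-5p, let-7i, miR-99a, miR-155-5p, miR-10a-5p, miR-30a-3p and miR-4334-3p lost their call when 1 library was left out, with adjusted p between 0.0527 and 0.183, as did miR-10b and miR-10a-3p, miR-30c-3p in 1 of 15 runs and miR-30c-1-3p in 13 of 15. Without 1 library, the change of miR-127 became -3.99 and that of miR-504 -2.31 (both without newborn replicate 1), and that of miR-206 lay between -5.76 (newborn replicate 3) and -7.68 (day 30 replicate 3). Each library of both ages other than newborn replicate 3 ended at least 1 of the first 9 calls, and for miR-10a-5p and miR-30a-3p so did day 180 replicates 1 and 2 and day 360 replicate 2, and for miR-30a-3p day 360 replicate 1.

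From day 30 to day 60, no miRNA passed the threshold (edgeR; 18 miRNAs at an unadjusted p under 0.05; 0 with DESeq2, limma or voom). The let-7 family, which accumulates as cells differentiate, was higher: 8 of its 9 tested members had a positive log2 fold change, with a median of 0.78 (camera adjusted p = 0.00171; adjusted p = 0.104 with an estimated correlation). No member passed the test by itself, and 0 passed adjusted over the list alone. let-7i averaged 53982 normalised CPM at day 30 (31125 without day 30 replicate 3) and 92525.3 at day 60, and let-7f 14532.6 and 27291.6. miR-182 averaged 738 and 162 normalised CPM at these ages (unadjusted p = 0.00398, adjusted p = 0.406), the first mean resting on day 30 replicate 1 at 1707.75, with 198 and 307 in the others against 137, 173 and 178 at day 60.

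From day 60 to day 180, no miRNA passed the threshold (edgeR; 14 at an unadjusted p under 0.05; 3 with DESeq2, 0 with limma, 8 with voom). The DESeq2 calls, miR-210, miR-20b and miR-7857-3p, were lower at day 180. Without day 180 replicate 3, edgeR called 2, miR-22-3p and miR-30a-5p. The miR-99/100 family, whose members share clusters with let-7, was higher: all 5 tested members had a positive log2 fold change, with a median of 1.20 (camera adjusted p = 0.000413; adjusted p = 0.0905 with an estimated correlation). miR-99a averaged 6186.91 normalised CPM at day 60 and 14212.7 at day 180, miR-125a 7.31 and 20.3 (12.7 without day 180 replicate 1), and miR-125b, a regulator of haematopoiesis, 157 and 258. No member passed adjusted over the list alone.

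From day 180 to day 360, no miRNA passed the threshold (edgeR; 28 at an unadjusted p under 0.05; 8 with DESeq2, 0 with limma, 4 with voom). Of the 14 lists, 4 passed camera, and none did with an estimated correlation or with a minimum of 10 CPM, under which the muscle list had too few members to test. The muscle list was higher, with a positive log2 fold change in 4 of 4 members and a median of 2.34 (adjusted p = 0.000164; adjusted p = 0.257 with an estimated correlation). miR-206 averaged 1.51 normalised CPM at day 180 and 12.7 at day 360, miR-1 1.51 and 9.44; both passed adjusted over the list alone. Without day 180 replicate 1 their means at day 180 were 0.61 and 0.48. The erythroid list was higher in 5 of 6 members (adjusted p = 0.0328; adjusted p = 0.279 with an estimated correlation), with miR-182 at 133 and 447 normalised CPM, while miR-451 had a log2 fold change of -0.20 ± 0.74. The myeloid list was higher in 7 of 7 members, with a median log2 fold change of 0.44 (camera adjusted p = 0.0328, or 0.322 with an estimated correlation). Its miR-24-3p averaged 608 and 1698 normalised CPM. The day 360 libraries were at 2447, 697 and 1951, and day 180 replicate 1 was at 808. The mean log2 fold change over the myeloid members was 1.05, above their median. At day 360 miR-24-2-5p was at 61.3, 5.67 and 44.1, and miR-23a, also on the list, at 672, 329 and 551. All of these were lowest in day 360 replicate 2, as were miR-27b-3p and miR-23b, which are outside the list and described below. How far the myeloid call rests on this variation within an age was not tested. The miR-29 and miR-30 families were lower in 10 of 13 members (adjusted p = 0.0328; adjusted p = 0.279 with an estimated correlation), with miR-30a-5p at 1100 (485 without day 180 replicate 3) and 242 normalised CPM. The erythroid call was lost without any of 5 libraries (day 0 replicate 3, day 180 replicates 1 and 3, day 360 replicates 2 and 3), at adjusted p up to 0.183, and with a minimum of 10 CPM (adjusted p = 0.0973). The myeloid call was lost without any of 8 libraries (day 0 replicate 3, day 30 replicates 1 and 3, day 180 replicates 1 and 3, and each at day 360), at adjusted p up to 0.213, with a minimum of 10 CPM (adjusted p = 0.0631) and with no low-count filter (adjusted p = 0.0722). The miR-29 and miR-30 call was lost without day 180 replicate 3 or any library of day 360, at adjusted p up to 0.179, and with a minimum of 10 CPM (adjusted p = 0.0970). Runs with a library left out were filtered anew, and 14 or 15 lists were tested in them. Losses without a library of another age may come from the filter, the number of lists or the estimate of the spread. These were not told apart.

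From birth to day 360, 71 of 215 miRNAs changed, 26 up and 45 down. let-7i rose from 14401.3 ± 6758.46 to 159249 ± 27358.4 normalised CPM (log2 fold change 3.47 ± 0.54, SE, n = 3 per age; edgeR adjusted p = 0.000233), and let-7f by 3.24 ± 0.56. miR-148a-3p, which targets the DNA methyltransferase DNMT1, rose by 2.95 ± 0.83, miR-10a-5p by 2.85 ± 0.49, miR-182 by 2.63 ± 0.66, miR-2411 by 2.63 ± 0.50, miR-151-3p by 2.43 ± 0.65, miR-29a by 2.35 ± 0.41, miR-101, which targets EZH2, by 2.30 ± 0.76, and miR-99a by 2.27 ± 0.45. miR-210 changed by -6.21 ± 0.73 (adjusted p = 5.19e-05), miR-1296-5p by -5.36 ± 0.73, miR-199a-3p by -5.13 ± 0.63, miR-339-5p by -3.79 ± 0.48, miR-2320-5p by -3.73 ± 0.62, miR-7134-5p by -3.61 ± 0.55, miR-30a-5p by -3.44 ± 0.62, miR-4334-3p by -3.14 ± 0.45, miR-148b-3p by -2.99 ± 0.52 and miR-296-3p by -2.99 ± 0.62. Of the 71, 58 had no overlap between the ages. Of all tested miRNAs, 32.6% had none, against 10% by chance and 16.3% to 19.5% in the later age steps without calls.

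**Figure D3:**
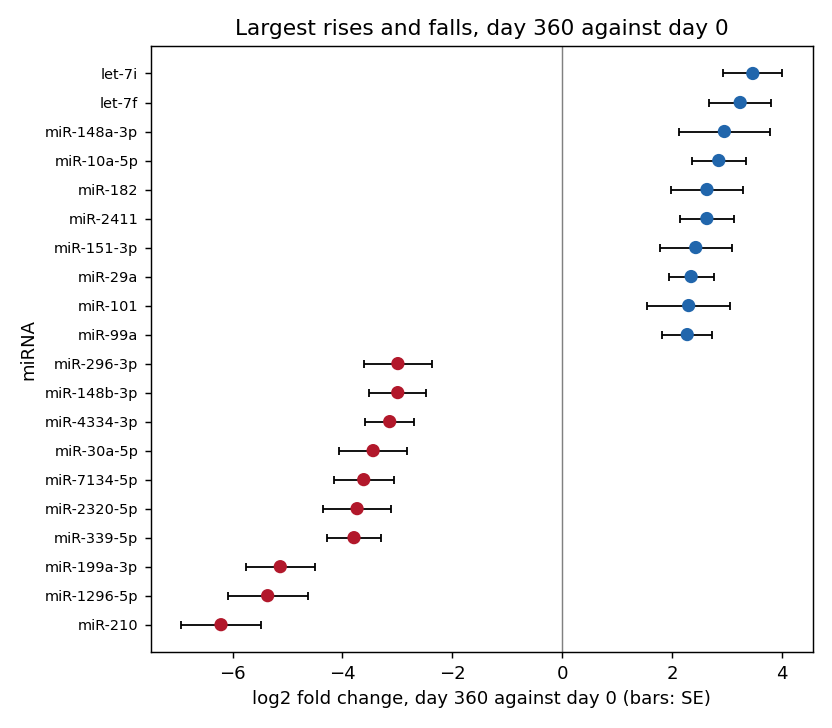
Log2 fold change from day 0 to day 360 of the 10 largest rises and 10 largest falls under the naming rule, with SE as bars. The rule asks for a call, at least 50 CPM at either age and no overlap between ages. Larger called changes of miRNAs outside the rule, such as miR-127, are left out. They run from -6.21 for miR-210 to 3.47 for let-7i.

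The let-7 family was higher at day 360 than at birth: 8 of 9 members had a positive log2 fold change, 4 rose (let-7i, let-7f, let-7d-5p and let-7g) and 6 passed adjusted over the list alone (camera adjusted p = 0.00966; adjusted p = 0.205 with an estimated correlation). No other list passed camera, but with no low-count filter the DLK1-DIO3 cluster was lower (adjusted p = 0.00359; 0.271 with an estimated correlation). In the lymphoid list, 2 of 10 tested members were called: miR-155-5p rose and miR-181a, which tunes T-cell receptor signalling, fell by 2.07 ± 0.65 on the log2 scale, and in the platelet list miR-151-3p rose while miR-199a-3p, miR-199a-5p and miR-221-3p fell. In the innate immune response list, miR-155-5p rose and miR-221-3p fell, and miR-146a-5p, a brake on NF-kB signalling, did not pass (0.90 ± 0.36, adjusted p = 0.0602). In the myeloid list, of 7 tested members, miR-24-1-5p rose and miR-145-5p fell, and in the erythroid list miR-182 rose, 1 of 6 tested members. In the miR-17~92 list, miR-19a, miR-19b, miR-18b and miR-20b were called. miR-19b was at 11.2, 94.2 and 3.51 normalised CPM in the day 360 libraries and miR-19a at 1.52, 14.8 and 0.527, and without day 360 replicate 2 neither was called (adjusted p = 0.455 and 0.207). The miR-29 and miR-30 families held 2 risers, miR-29a and miR-29b, and 5 fallers, all from miR-30. miR-10a-5p and miR-10a-3p rose in the HOX loci list, miR-99a in the miR-99/100 family, and miR-7 and miR-128 in the brain list. In the muscle list miR-499-5p rose and miR-133a-3p fell. None of the 3 tested members of the miR-15/16 family and none of the 5 liver members passed. The epithelial list had no tested member, and the DLK1-DIO3 cluster had only miR-127 after the low-count filter, which fell by 7.01 ± 1.21 on the log2 scale.

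Of the called miRNAs, 26 of 71 were higher at day 360. With the scaling alone changed, 29 of 67 were with DESeq2 size factors and 13 of 96 with library totals. Where the test changed too, 9 of 75 were with limma on TPM and 45 of 90 with DESeq2. The count was 125 without newborn replicate 3 and 46 without newborn replicate 2, and miR-101 and miR-148a-3p lost their calls without newborn replicate 2 (adjusted p = 0.0975 and 0.0549); miR-101 also did without newborn replicate 1 (adjusted p = 0.0997) and day 360 replicate 2 (adjusted p = 0.118). Among the list members above, let-7g (adjusted p up to 0.115), miR-10a-3p, miR-24-1-5p, miR-128 and miR-7 lost their calls without newborn replicate 2, let-7g and miR-10a-3p without newborn replicate 1, let-7g without day 360 replicate 2, and miR-221-3p without day 360 replicate 1 (adjusted p = 0.0847). miR-181a lost its call without newborn replicates 1 or 2 or day 360 replicates 1 or 3 (adjusted p up to 0.124), and miR-499-5p without any of 11 libraries, day 0 replicate 3, day 30 replicate 1 and day 60 replicates 1 and 2 being the exceptions (adjusted p up to 0.157). Of list members outside the naming rule, named after their values were seen, miR-18b lost its call in 12 of 15 runs (adjusted p up to 0.161), miR-29b in 10 (0.253), miR-30b-3p in 8 (0.188), miR-20b in 5 (0.116), miR-19b in 3, miR-19a in 2, and miR-145-5p and miR-30c-1-3p in 1.

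Single libraries also moved the size of some changes. Without newborn replicate 3, log2 fold changes were 5.09 for miR-7, 4.63 for miR-148a-3p, 4.31 for miR-101 and let-7f, 3.22 for miR-499-5p and 2.08 for let-7g. Without day 360 replicate 2, miR-151-3p rose by 3.13 and miR-296-3p changed by -2.28. miR-210 changed by -7.16 without day 360 replicate 1, and miR-127 by -6.40 and miR-181a by -1.46 without newborn replicate 1.

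The comparisons of days 30 and 360 with day 0 shared their newborn libraries. They had 8 rises and 23 falls in common, against 1.09 and 5.44 for independent lists and a mean of 0.02 in simulations of unchanged groups, in which almost no miRNA is called, so that the last value sets no level for the overlap. Their log2 fold changes correlated across miRNAs, which are not independent, at r = 0.796 (0.492 in the simulations), with a covariance of 2.43 (0.238 in the simulations). Part of the overlap may come from the shared newborn libraries, which are too few to split.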

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

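The voom weighting and the keeping of repeated miRNAs were chosen after seeing the data. Apart from miR-7136-5p, no named miRNA or list changed direction under any alternative run. Across the 5 ages, 61 miRNAs were called, 150 with voom and library weights, and 37 to 126 when each library was left out in turn. At day 30 against day 0, the count of 35 became 12 with the libraries of both ages only, 22 with limma on TPM, 56 with DESeq2 and 130 with voom, and 16 to 126 with each library left out. At day 180 against day 60 it went from 0 to 3 with DESeq2 and 8 with voom, and 0 to 2 with each library left out. At day 360 against day 180 it went from 0 to 8 with DESeq2 and 4 with voom. At day 360 against day 0, the count of 71 became 26 with the libraries of both ages only and 124 with voom, and 46 to 125 with each library left out. Voom gave newborn replicate 3 a weight of 0.0893. The fit on both ages alone has fewer libraries to estimate the spread; for the others the cause was not tested. Keeping the 2 repeated miRNAs gave 56 calls across ages, 35 at day 30 against day 0 and 71 at day 360 against day 0. Relative to TMM, the median log2 fold change of day 360 against day 0 moved by 0.27 with DESeq2 size factors and by -1.02 with library totals. For day 30 against day 0 it moved by 0.14 and -0.20. Of 52 named results, none lost its call without newborn replicate 3, and 22 lost it without some other library. All 7 list calls were lost with an estimated correlation, though the miR-99/100 call at day 180 against day 60 then passed with DESeq2 size factors (adjusted p = 0.0401), a minimum of 10 CPM (0.0347) or repeated miRNAs kept (0.0259). Fry asks whether members move 1 way on balance, not against other miRNAs, and passed 1 of these 7, the let-7 family at day 360 against day 0 (adjusted p = 0.000108). It also passed the erythroid, platelet, HOX loci, liver and brain lists there, and the let-7, erythroid, innate immune response, muscle and brain lists at day 30 against day 0, with none in the later steps. With a minimum of 10 CPM, the erythroid, myeloid and miR-29 and miR-30 calls at day 360 against day 180 were lost (adjusted p = 0.0973, 0.0631 and 0.0970) and the muscle list had too few members to test; with no low-count filter the myeloid call was lost (adjusted p = 0.0722). The number of lists called at day 30 against day 0 was 0, 7 with no low-count filter and 0 to 1 with each library left out. At day 360 against day 0 it was 1, 2 with no low-count filter and 1 with each library left out. In the later steps it was 1 to 3 at day 60 against day 30, 1 to 4 at day 180 against day 60 and 1 to 4 at day 360 against day 180. These ranges leave out the DLK1-DIO3 cluster, which such runs could test only through newborn replicates 1 and 2. The replicate numbers mark no shared animal or litter in the labels. Same-numbered libraries deviated together with r from -0.547 to 0.409, above 0.1 in 10 of 30 pairs, and 4 of 15 libraries correlated best with their own number. With the replicate block, 49, 27, 0, 0, 0 and 66 miRNAs were called across ages, at day 30 against day 0, in the 3 later steps and at day 360 against day 0. With 3 libraries per age, about 4-fold changes were needed for a call to be as likely as not in simulated data, so smaller changes are mostly beyond this depth and replication.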

Other observations

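The slopes on age, the other pairs of ages, the miR-27b-3p values, the tests of the most abundant miRNAs and of red-cell RNA, and the tests of scaling were chosen after the results were seen; the older-animal and depth tests and the counts of splits were written before. The slopes were computed with 3 scalings and the other pairs were 5 comparisons. Among the older animals alone, day 30 to day 360, 14 of 209 miRNAs had a slope on log2 day (edgeR, adjusted p under 0.05), 10 upward and 4 downward; with library totals 65 had, 2 upward and 63 downward, at a median slope of -0.26 against 0.02. miR-210 had a slope of -1.31 ± 0.16 log2 units per doubling of age (SE; adjusted p = 0.000154) and let-7f one of 0.50 ± 0.09. miR-206, a skeletal-muscle miRNA, had a slope of 1.88 ± 0.29 without a steady rise, with averages of 0.28, 0.104, 1.51 and 12.7 normalised CPM at days 30, 60, 180 and 360, the first 2 below the level of 3 counts (0.301 to 0.52 CPM before scaling). let-7i, let-7a, miR-10a-5p, miR-10b, miR-101, miR-125a, miR-1468 and miR-2411 also had upward slopes, and miR-148b-3p, miR-2320-5p and miR-7857-3p downward ones. Of the upward slopes, only those of let-7f and miR-206 stayed called with library totals (edgeR adjusted p = 0.0459 and 0.000874). The others were then at adjusted p from 0.0526 (miR-1468) to 0.746 (let-7a). Of the other pairs of ages, day 60 and day 180 each differed from day 0 in 48 miRNAs, day 360 differed from day 60 in 7, day 360 from day 30 in 2 (miR-206 and miR-210) and day 180 from day 30 in 1 (miR-210).

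miR-27b-3p varied between libraries of the same age: 1034, 8187.98 and 10639.8 normalised CPM at day 0, and 6014.87, 1150.99 and 3623.6 at day 360. miR-23b, from the same cluster, was at 125, 1044.87 and 1435.01 normalised CPM at day 0, and at 1016.9, 148 and 669 at day 360. miR-24-2-5p was at 0.547, 7.29 and 15.5 normalised CPM at day 0, and at 61.3, 5.67 and 44.1 at day 360. They were singled out after their values were seen, in a search through correlations with miR-27b-3p. Across the 5 ages miR-27b-3p was among the 61 called (adjusted p = 0.0387), and miR-24-2-5p and miR-23b were not (adjusted p = 0.0651 and 0.185); the spread within an age was not tested.

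Newborn replicate 3 differed from newborn replicates 1 and 2. More red-cell RNA stays open. miR-451 and miR-144 were higher in newborn replicate 3 by 3.36 and 4.22 on the log2 scale. miR-486, another abundant red-cell miRNA, differed by -2.17 (SD within older ages 0.46). These values go opposite ways and the rule was set after they were seen, so they decide nothing. The share taken by the most abundant miRNAs stays open. For this test 5 miRNAs were left out by their largest share of any library: miR-451, miR-148a-3p, miR-92a, let-7i and miR-486. They include miR-486 in place of miR-7, which has the higher mean normalised CPM. Without these 5 the smaller difference was 1.45, with a bootstrap interval of 1.24 to 1.71, and the largest of other pairs was 1.28. A library from an older animal also stays open: of 119 miRNAs separating newborn replicates 1 and 2 from the 12 older libraries, 27.7% lay beyond all older libraries on the newborn side in replicate 3 (95% exact interval 19.9% to 36.7%), above the 7.69% of an older library, but not clearly above the 25% set in advance to exclude one, and the miRNAs are not independent. In that library, 67 of the 119 lay within the older range, and 19 lay beyond it on the side away from newborn replicates 1 and 2. A difference between newborn animals was not tested.

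For day 360 against day 0, library depth is argued against as the whole cause, because 63 miRNAs were called with all libraries thinned to 5771711 counts, against 71. For the falling miRNAs, 38 of 45 stayed called with DESeq2 size factors. These moved the median log2 fold change by only 0.27 relative to TMM, and library totals moved it by -1.02. A small upward shift and a downward one test the falls little, so scaling stays open for the falls taken alone. For the rising miRNAs taken alone scaling also stays open, because 13 of 26 stayed called with library totals. Scaling moves all miRNAs of a library alike, yet both directions were called with each. There were 29 higher and 38 lower with DESeq2 size factors, and 13 and 83 with library totals. This argues against scaling as the cause of both directions together. For slopes from day 30 to 360, scaling may account for part of the rises, since 2 of 10 stayed called with library totals; the 4 falling miRNAs stayed called with DESeq2 size factors, which did not move the median slope, so this decides nothing. The slope count of 14 ran from 3 to 21 with each library left out (5, 3 and 19 without day 30 replicates 1, 2 and 3, and 21 and 7 without day 360 replicates 2 and 3), and age is the untested biological explanation.

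Other groupings of the libraries were compared with the real ones. Across ages, only the real grouping among 100 called as many as 61 miRNAs (highest other 46). That share is the smallest that 100 groupings can give, so chance is argued against but not excluded. For the slopes, the real ages were likewise the only 1 of 100 to call 14 (highest other 9). These slopes were chosen after the results were seen, and their count was 3 without day 30 replicate 2. With 3 libraries against 3, 10 splits cannot give a share under 0.05. At day 30 against day 0, 2 of 10 splits called 35 or more (real 35, highest other 35), and at day 360 against day 0, 2 of 10 called 71 or more (real 71, highest other 74). Of the 3 splits that set newborn replicates 1 and 2 with 1 older library against the rest, those with day 30 replicates 1, 2 and 3 called 35, 1 and 0, and those with day 360 replicates 1, 2 and 3 called 0, 0 and 74. For the 3 later steps, all 10 splits called at least the real 0, with a highest other of 1 at day 60 against day 30 and 0 at the others.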
